A study of Mus musculus with 36 samples.

How the data were processed

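RNA was measured in 36 libraries from C57BL/6 mice aged 8 weeks. Of these, 28 came from 8 cell populations sorted by flow cytometry from homogenates of the brain subependymal zone (SEZ), the adult neurogenic niche lining the lateral ventricles, and 8 from 2 populations sorted from cultured neurosphere cells. Per the labels' protocols, poly(A) RNA was made into libraries with the SMARTer Ultra Low kit and Nextera XT adapters and sequenced on a NextSeq system. This kit does not mark strand. The submitters' processing notes name FastQC, cutadapt, Trimmomatic, HISAT2, featureCounts and limma and the builds GRCm38 and mm10, with no roles or order. Their versions, the gene annotation, the filters and the sorting gates are not given in the sources used here.

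The authors deposited 1 table of log2 values for 19909 Ensembl genes, with 1 column for each library, and no column of another sample. Its unit was worked out from the values, since no header names it. In every column, 2 raised to the deposited log2 values sums to between 987637 and 987910, so the scale resembles log2 CPM (counts scaled to a common library total). Each library has a negative floor, between -5.06 and -2.18, shared by its lowest genes, and the low values rise in steps, as whole reads would leave. All 36 columns have nearly the same distribution, with medians from 3.53 to 3.56, as quantile normalization of all columns together by the authors would leave. Quantile normalization assumes that each population holds the same spread of RNA levels, so a change in total RNA per cell cannot be seen, and a shift of many genes one way appears in part as a shift of the others the opposite way. Total reads are not given. The number of distinct steps up to the median gene, which follows depth, ran from 55 (Other replicate 3) to 426 (DFFDA_H replicate 4). The genes at a library's floor ran from 362 to 3932. A fold change of a gene at the floor in some libraries depends on where that floor lies.

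The table also ended with 1770 blank lines, which were dropped, and 23 gene symbols had been turned into dates by a spreadsheet, so genes were followed by Ensembl identifier. Of the identifiers, 19863 matched GENCODE release M21 (GRCm38), from which coordinates were taken. Genes that overlap another model, have an antisense partner or have a near-identical copy are uncertain, since how the authors assigned such reads is not given in the sources used here.

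Groups and replicate numbers came from the labels. The labels call the samples biological replicates without saying that each came from a separate animal or culture, so p-values measure the spread between these samples. The design foresaw a count model for raw counts and limma for log values, and the limma branch was used because the table holds log values. One linear model with a mean for each of the 8 freshly sorted populations was fitted to the 28 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings), and a separate model to the 8 neurosphere libraries. Genes were kept when their log2 value was at least 0 in at least 3 libraries of 1 group, which left 17788 and 15956 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene with adjusted p under 0.05 was called changed. The 9 comparisons followed the labelled sequence qNSC, pNSC, aNSC, NPC1, NPC2, NB1, NB2, with qNSC against aNSC, the population labelled Other against the equally weighted mean of the 7 named populations, and DFFDA_H against DFFDA_L.

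Before the data were examined, 29 gene lists (698 members, 680 of them found) were fixed: surface antigens commonly used for sorting, astroglial, activated stem cell and neuroblast genes, S phase, G2 and M phase, CDK inhibitors, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, glycolysis, fatty acid oxidation, cholesterol synthesis, lysosome, TNF and NF-kB signalling, interferon response, Notch signalling, BMP signalling, adhesion and matrix, immediate early genes, mitochondrially encoded transcripts, and markers of microglia, endothelium, mural cells, oligodendrocytes, oligodendrocyte precursors, ependyma, mature neurons and red cells. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 260 list tests, of which 116 passed. With a correlation estimated from the data 15 passed. Members are counted past the threshold over all genes tested and again adjusted over the list alone. Named genes were chosen by a rule fixed at the same time: the surface antigens, Mki67, Cdkn1a, Cdkn1b, Tnfrsf1a and Tnfrsf1b in every comparison; the 6 largest changes each way among called genes with a log2 value of at least 4.3 in the higher group, no overlap between the libraries of the groups and an ordinary symbol; and up to 4 members of each called list with the smallest p. The text names the first 2 kinds and part of the third.

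The position of a library between qNSC and aNSC was the mean of the genes higher in aNSC less the mean of those lower, scaled so that the qNSC mean was 0 and the aNSC mean 1, with an exact permutation test for the neurosphere populations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on data simulated from the real genes' means and spreads, with normal noise, in which 50 genes each were shifted by log2 0.5, 1, 2 and 3. It recovered 10%, 42%, 68% and 84% of them at the pNSC to qNSC sample sizes, with 5 false calls; 6%, 32%, 66% and 86% for NPC2 and NPC1, with 2 false calls; and 28%, 76%, 92% and 100% for the neurosphere groups, with 4 false calls. Shifts of log2 0.5 were therefore mostly missed in the simulated data. Far fewer genes were shifted there than were called for pNSC against qNSC (3959) or between the neurosphere groups (6995). The Benjamini-Hochberg adjustment is stricter when few genes change, so the simulated recovery does not carry over to those comparisons. Of their calls, 1800 and 1837 were over 2-fold and the rest were smaller. The simulation gave each gene the same spread in all groups of a fit. Real qNSC and pNSC libraries were less alike, with correlations down to 0.879 and 0.901 against 0.962 in aNSC. The simulated false calls therefore do not bound those of the real comparisons. To see whether other divisions give as many calls, the libraries of each pair of groups were split in every other way at the same group sizes with the rest of the fit kept, and for Other 100 draws of 3 libraries were set against the remaining 25 in a fit of 2 groups. Alternatives covered normalization, filter, trend, the libraries in the fit, the replicate number as a block and each library left out in turn. Added after seeing the data were library weights, a common floor, centring, a correction for GC content and length, a higher filter, removal of 3 libraries and a paired test of positions. Results of 4 genes are not reported here, among them 1 library value that stood apart and is kept in the counts.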

Results

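The libraries separated first by origin and then along the labelled stem cell sequence. The 8 neurosphere libraries lay apart from the 28 freshly sorted libraries on the first principal component, which held 45.6% of the variance. The second component held 22.7% and ran from the libraries labelled qNSC through pNSC and aNSC to the NPC and NB populations. Transcripts of the astrocyte and stem cell glutamate transporter Slc1a3 were most abundant in qNSC and pNSC, those of the growth factor receptor Egfr in aNSC, and those of the surface protein Cd24a, which neuroblasts carry, in NB2. These belong to the surface antigens commonly used for sorting. Since the sorting gates are not given, differences in such antigens, here and below, may follow from the sort itself. The labels describe qNSC, pNSC, aNSC, NPC1, NPC2, NB1, NB2 and Other only by these names, and the 2 neurosphere populations as DFFDA_H and DFFDA_L, cells that were loaded with the dye DFFDA, grown for 4 days with EGF and FGF and then sorted. The qNSC, pNSC, aNSC, NPC1, DFFDA_H and DFFDA_L groups had 4 libraries each and the others 3.

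**Figure D1:**
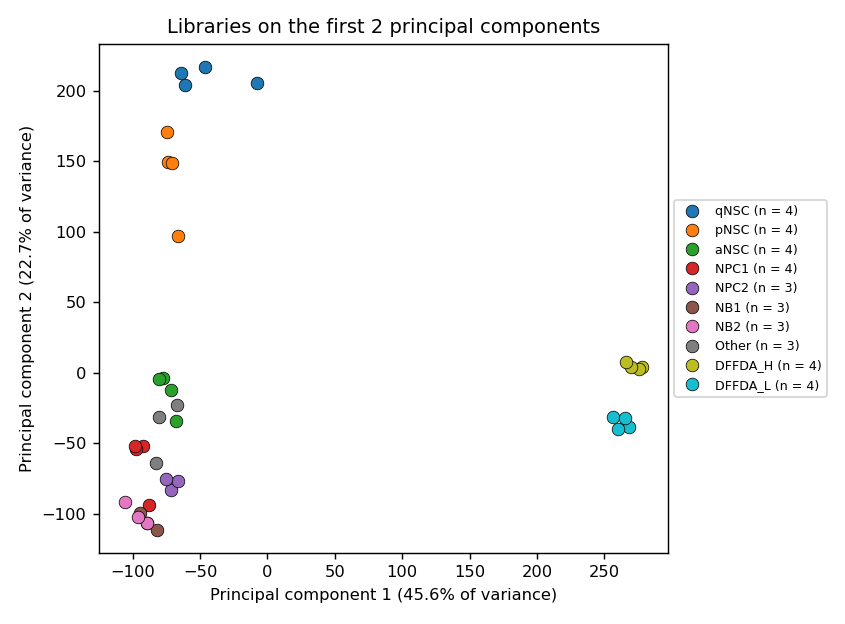
Principal component 1 (45.6% of variance, horizontal axis) against component 2 (22.7%, vertical axis), 1 point per library, coloured by population. The 8 neurosphere libraries lie between 256.1 and 278.1 on component 1, and the 28 freshly sorted libraries all lie below 0 on it.

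Depth and likeness differed between populations. The qNSC libraries had 1159 to 3932 genes at their floor and a median gene 99 to 144 steps above it, and the correlation of a qNSC library with the others of its group ran from 0.879 to 0.959. In pNSC the floor held 1275 to 2319 genes, and correlations ran from 0.901 to 0.948. In aNSC it held 780 to 1183 genes (0.962 to 0.974), in NPC1 617 to 777 (0.961 to 0.976), in NPC2 1170 to 1684 (0.952 to 0.966), in NB1 1082 to 1400 (0.958 to 0.969), in NB2 989 to 1364 (0.964 to 0.971) and in Other 1014 to 1836 (0.922 to 0.945). The neurosphere libraries were deepest, with 362 to 604 floor genes in DFFDA_H and 365 to 515 in DFFDA_L and correlations of at least 0.981. These correlations are across genes, which are not independent replicates.

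**Figure D2:**
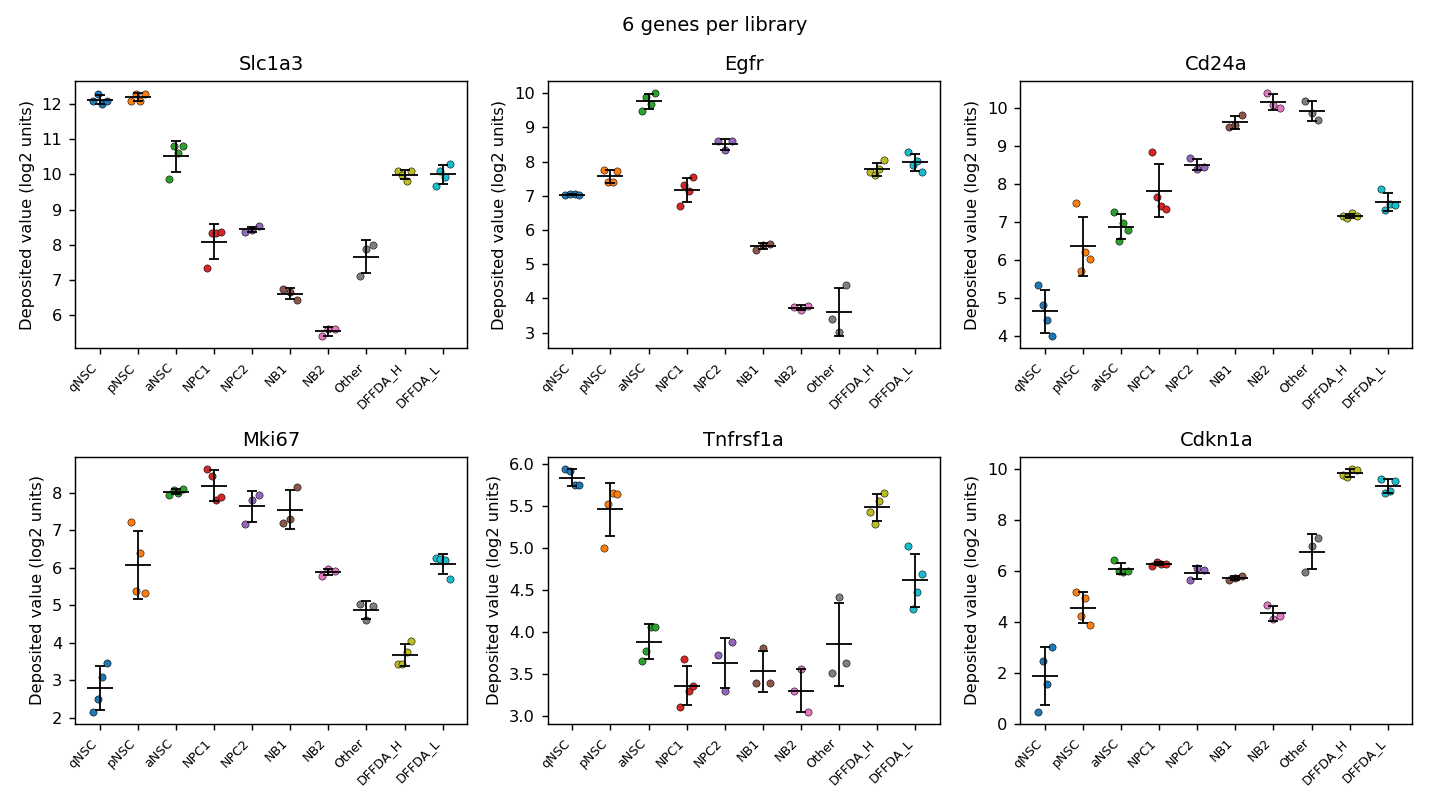
Deposited log2 value (vertical axis) of 6 genes in each of the 36 libraries by population (horizontal axis), with points for libraries and bars for mean ± SD. Mki67 averages 2.81 in qNSC, 6.08 in pNSC and 8.03 in aNSC, and Tnfrsf1a 5.84, 5.46 and 3.88.

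The step from qNSC to pNSC, adjacent stem cell labels, was marked by more cell cycle, neuroblast and immediate early transcripts in pNSC with little change in the astroglial set. With an estimated correlation the cell cycle lists kept their camera calls, and the neuroblast and immediate early lists lost theirs. Mki67, which is transcribed in cycling cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), averaged 6.08 ± 0.91 in pNSC and 2.81 ± 0.586 in qNSC (log2, SD, n = 4 each), 9.67-fold higher. The replication licensing gene Mcm5 (ENSMUSG00000005410, chromosome 8, 75109569 to 75128439), the nucleotide synthesis gene Rrm2 and the spindle gene Tpx2 were 10.1-fold, 6.45-fold and 9.42-fold higher. Mycn was 6.81-fold higher, and the neuroblast transcription factor gene Dlx2 and the RNA-binding protein gene Elavl4 were 5.45-fold and 8.47-fold higher. The activity-induced genes Egr1 and Ier2 were 6.44-fold and 10 times as high, and the CDK inhibitor Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) 6.37-fold. None of these genes overlapped between the 4 libraries of each group, and their limma adjusted p-values (Benjamini-Hochberg) were 6.96e-06 or less.

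Of the genes tested, 3959 changed from qNSC to pNSC, 2525 higher and 1434 lower in pNSC, 1800 of them over 2-fold. The largest increases were those of Egr2, the Notch ligand Dll1, the mitotic genes Ndc80 and Aurkb, the replication gene Dtl and the checkpoint kinase Chek1, at log2 4.26 to 4.78. Each of these 6 had 1 or 2 qNSC libraries at the floor, so their sizes depend on it. The largest decreases were those of Stambpl1, the chloride channel gene Ttyh2, the homeobox genes Nkx6-2 and Nkx2-2, the retinoic acid receptor Rarb and B3galt2, at log2 -2.99 to -1.9, with pNSC replicate 1 at the floor for Stambpl1, so that its size depends on that library. The Ttyh2 call (adjusted p 0.0107, with 0.00293 to 0.161 over the alternatives) ended without pNSC replicate 1, at 0.0699. With only the 2 groups fitted, the limma calls of Egr2 (0.0558), Stambpl1 (0.174) and Rarb (0.0559) also ended; over all alternatives their adjusted p-values ran from 7.13e-05 to 0.0558, 0.00165 to 0.174 and 0.000732 to 0.0559. Library weights ended that of Nkx2-2, at 0.0995 (3.91e-05 to 0.0995 over the alternatives). The count of changed genes was 1380 with only the 2 groups fitted, 2234 with library weights and 2429 without pNSC replicate 1. The share of calls that were higher, 63.8%, was 50.7% when libraries were centred on a trimmed mean, which moved the median over all genes from -0.05 to -0.14. The share moved by over 10 points in 4 of the alternative and left-out fits, centring among them.

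Among the surface antigens, Cd24a (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265) was 3.29-fold higher in pNSC (limma adjusted p 0.000309). Slc1a3 and Cd9 did not pass (0.812 and 0.458). Egfr lay just outside the threshold (0.0506; 0.0321 to 0.125 over the alternatives) and passed without pNSC replicate 3 (0.0491). Prom1 lay just inside it (0.0497; 0.0365 to 0.217 over the alternatives) and its call ended without qNSC replicate 1 (0.201), 3 (0.0535) or 4 (0.065) or without pNSC replicate 2 (0.185) or 3 (0.0739). Cdkn1b (0.322), Tnfrsf1a (0.197) and Tnfrsf1b (0.753) did not pass.

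In the lists, 41 of 42 S phase genes and 51 of 52 G2 and M phase genes were higher in pNSC, with the same counts adjusted over the list alone and camera adjusted p of 5.05e-33 and 6.06e-45. Both also passed with an estimated correlation (0.0424 and 0.0229). Of 13 activated stem cell genes 9 were higher (10 adjusted over the list alone; camera adjusted p 3.64e-09, and adjusted p = 0.0229 with an estimated correlation). Of 26 neuroblast genes 21 were higher (23 adjusted over the list alone; camera 7.58e-16, adjusted p = 0.115 with an estimated correlation). Of 27 immediate early and dissociation stress genes 20 were higher (21 adjusted over the list alone; camera 1.46e-11, adjusted p = 0.127 with an estimated correlation). Ribosome biogenesis genes such as Fbl, 2.71-fold, were higher in 20 of 30 (22 adjusted over the list alone; camera 2.2e-10, adjusted p = 0.0229 with an estimated correlation), and ribosomal protein genes such as Rpl4, 1.94-fold, in 44 of 79 (61 adjusted over the list alone; camera 5.28e-15, adjusted p = 0.513 with an estimated correlation). The 30 astroglial genes did not shift as a set (camera adjusted p 0.164), with 1 lower gene. CDK inhibitors were higher in 3 of 6, also adjusted over the list alone (camera 0.00771, adjusted p = 0.151 with an estimated correlation), and missed the threshold among genes with a mean of at least 4 (0.0923; 0.00584 to 0.151 over the alternatives).

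Microglia markers were also higher in pNSC, with a median log2 change of 1.87 over 20 genes, 6 of them past the threshold and 12 adjusted over the list alone (camera adjusted p 0.000723, adjusted p = 0.586 with an estimated correlation). Without qNSC replicate 1 its median was 0.837 (camera adjusted p 0.0453). The list did not pass with library weights (0.101) or among genes with a mean of at least 4 (0.151), with 0.000136 to 0.586 over the alternatives. The microglial receptor gene Csf1r, at 0.0147, ended without qNSC replicate 1 (0.0743). Gpr34, at 0.0204, also ended without it (0.102), and the complement gene C1qc, at 0.0266, ended without it (0.0902) and without pNSC replicate 3 (0.0604). These 3 were 3.7-fold, 6.49-fold and 7.29-fold higher by limma, the latter 2 with qNSC replicate 1 at the floor, and over the alternatives their adjusted p-values reached 0.25, 0.295 and 0.286. Mature neuron and erythroid markers were lower in pNSC, in 2 of 16 and 2 of 5 (2 and 4 adjusted over the list alone; camera 0.0384 and 0.0405, adjusted p = 0.513 and 0.552 with an estimated correlation). Both calls ended without qNSC replicate 2 (0.273 and 0.0955), pNSC replicate 3 (0.139 and 0.0675) or pNSC replicate 4 (0.0508 and 0.157), with ranges of 0.0234 to 0.584 and 0.0165 to 0.552 over the alternatives.

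Between pNSC and aNSC astroglial transcripts fell while Egfr and replication transcripts rose. The apolipoprotein gene Clu (ENSMUSG00000022037, chromosome 14, 65968483 to 65981547) averaged 12.6 ± 0.0975 in pNSC and 5.13 ± 0.686 in aNSC (SD, n = 4 each), a log2 change of -7.5, and the secreted protease gene Htra1 changed by -5.94. Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158) was 4.56-fold higher in aNSC, at 9.76 ± 0.228 against 7.57 ± 0.195. Slc1a3 (ENSMUSG00000005360, chromosome 15, 8634124 to 8710764) and Cd9 were lower, by log2 -1.71 and -0.835. The TNF receptor Tnfrsf1a (ENSMUSG00000030341, chromosome 6, 125349362 to 125362484) was lower by -1.58, while Mki67 and Cdkn1a were 3.85-fold and 2.88-fold higher. The adjusted p-values of these 8 genes by limma were 0.0011 or less, with no overlap between the groups. Cd24a did not pass (0.178, with 0.0053 to 0.417 over the alternatives) but did without pNSC replicate 1 (0.0115). Prom1 did not pass (0.141) except without pNSC replicate 2 (0.0369). Cdkn1b (0.853) and Tnfrsf1b (0.675) did not pass, though Tnfrsf1b did with values below 0 set to 0 (0.045; 0.045 to 0.928 over the alternatives).

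In all, 8585 genes changed between pNSC and aNSC, 5044 higher and 3541 lower in aNSC, 5188 of them over 2-fold. The largest increases among the named set included those of the Notch ligand Dll4, the helicase Ercc6l, Olfm2 and the transcription factors Olig2 and Gsx1, at log2 3.39 to 3.92, with pNSC replicate 1 at the floor for Dll4, so that its size depends on that library. Slc14a1, Gjb6, Gdf10, Agt and Cd38 had the largest decreases, at log2 -9.58 to -8.96, with 1 or 2 aNSC libraries at the floor each. Kirrel2, at 4.44 in pNSC, was listed at the floor in all 4 aNSC libraries. The share of calls that were higher, 58.8%, was 45.9% under trimmed-mean centring, which moved the median over all genes from 0.22 to 0.02, and 5314 genes passed when only genes with a mean of at least 4 were tested.

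All 30 astroglial genes were lower in aNSC, also adjusted over the list alone (camera adjusted p 1.48e-25, adjusted p = 0.0738 with an estimated correlation). Lysosome genes such as Tpp1 and Ctsb, at -2.76 and -1.72, were lower in 27 of 29, also adjusted over the list alone (camera 2.05e-17, adjusted p = 0.0229 with an estimated correlation). Fatty acid oxidation genes such as Acsl6, at -3.83, were lower in 19 of 22 (20 adjusted over the list alone; camera 5.84e-13, adjusted p = 0.0511 with an estimated correlation). Adhesion and matrix genes such as Timp3, at -4.59, were lower in 17 of 22, also adjusted over the list alone (camera 4.98e-08, adjusted p = 0.0985 with an estimated correlation). BMP signalling and Id genes such as Id3, at -3.61, were lower in 6 of 14 (7 adjusted over the list alone; camera 0.00295, adjusted p = 0.0985 with an estimated correlation).

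Higher in aNSC were 42 of 42 S phase genes, Mcm6 5.13-fold among them, also adjusted over the list alone (camera adjusted p 1.92e-18, adjusted p = 0.108 with an estimated correlation), and 49 of 52 G2 and M phase genes, Cdk1 4.39-fold among them (51 adjusted over the list alone; camera 1.6e-13, adjusted p = 0.211 with an estimated correlation). The Notch pathway gene Hes6 was 5.02-fold higher, and 10 of 13 activated stem cell genes rose, also adjusted over the list alone (camera 0.00332, adjusted p = 0.209 with an estimated correlation). Ribosome biogenesis genes, Ncl 2.98-fold among them, rose in 28 of 30 (29 adjusted over the list alone; camera 8.8e-11, adjusted p = 0.0229 with an estimated correlation). Ribosomal protein genes rose in 78 of 79, Rpl4 by 2.74-fold, also adjusted over the list alone (camera 5.9e-16, adjusted p = 0.501 with an estimated correlation). The neuroblast genes Stmn2 and Gad1 were lower in aNSC by log2 -3.24 and -2.47, though the list's call rested on pNSC replicate 1 (camera 0.0227, adjusted p = 0.309 without it and adjusted p = 0.679 with an estimated correlation, the top of the range from 0.0142 over the alternatives). Microglia markers, Trem2 by -2.76 among them, were lower in aNSC in 7 of 20, also adjusted over the list alone (camera 0.00409, adjusted p = 0.655 with an estimated correlation), and did not pass among genes with a mean of at least 4 (0.0923; 2.4e-05 to 0.655 over the alternatives).

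Across the whole interval from qNSC to aNSC, 11090 genes changed, 6276 higher and 4814 lower in aNSC, 8071 of them over 2-fold. Mcm5 was 47 times and Mki67 37.3 times as high in aNSC, Tpx2 33.2 times, Egr1 39.4 times, Ier2 25.5 times and Mycn 14 times. Egfr, Cd24a and Prom1 were 6.62-fold, 4.73-fold and 1.82-fold higher, and Slc1a3, Cd9 and Tnfrsf1a lower by log2 -1.63, -0.97 and -1.96. Cdkn1a was 18.4-fold higher. Limma gave all of these adjusted p-values of 0.000321 or less. Cdkn1b (0.152, with 0.0249 to 0.708 over the alternatives) and Tnfrsf1b (0.966) did not pass. The bHLH gene Helt, the Notch ligands Dll4, Dll1 and Dll3, Dtl and Ccnf had the largest increases, log2 6.74 to 7.89, and the transporter genes Slc14a1 and Atp13a4 with Cd38, Gjb2 and Agt the largest decreases, log2 -10.3 to -9.75, with floor libraries in the lower group for all but Dll3. Kirrel2 was again listed at the floor in aNSC. Clu was lower by log2 -7.59. Of the calls, 56.6% were higher, against 44.9% under trimmed-mean centring, which moved the median over all genes from 0.19 to -0.11, and 6539 genes passed among those with a mean of at least 4.

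Ribosomal protein genes, 78 of 79 of them, were higher in aNSC than in qNSC by a median log2 of 1.66, Rpl4 (ENSMUSG00000032399, chromosome 9, 64173375 to 64178666) 5.33-fold, also adjusted over the list alone (camera adjusted p 4.5e-18, adjusted p = 0.464 with an estimated correlation). They rose also relative to the shift of all genes under centring. Ribosome biogenesis genes, Dkc1 5.39-fold among them, rose in 28 of 30, also adjusted over the list alone (camera 3.67e-11, adjusted p = 0.0229 with an estimated correlation). Glycolysis genes such as Pfkp, at -3.74, were lower in 14 of 19 (15 adjusted over the list alone; camera 5.17e-05, adjusted p = 0.207 with an estimated correlation), and Acsl6 and Tpp1 fell by 4.09 and 3.08 on the log2 scale. Immediate early genes were higher in 17 of 27 (18 adjusted over the list alone; camera 0.00162, adjusted p = 0.553 with an estimated correlation). TNF and NF-kB genes split 5 higher and 5 lower, also adjusted over the list alone (camera 0.795, with a median of 0.16, a mean of -0.107 and a test direction of lower), and mature neuron markers did not pass as a set (0.098).

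**Figure D3:**
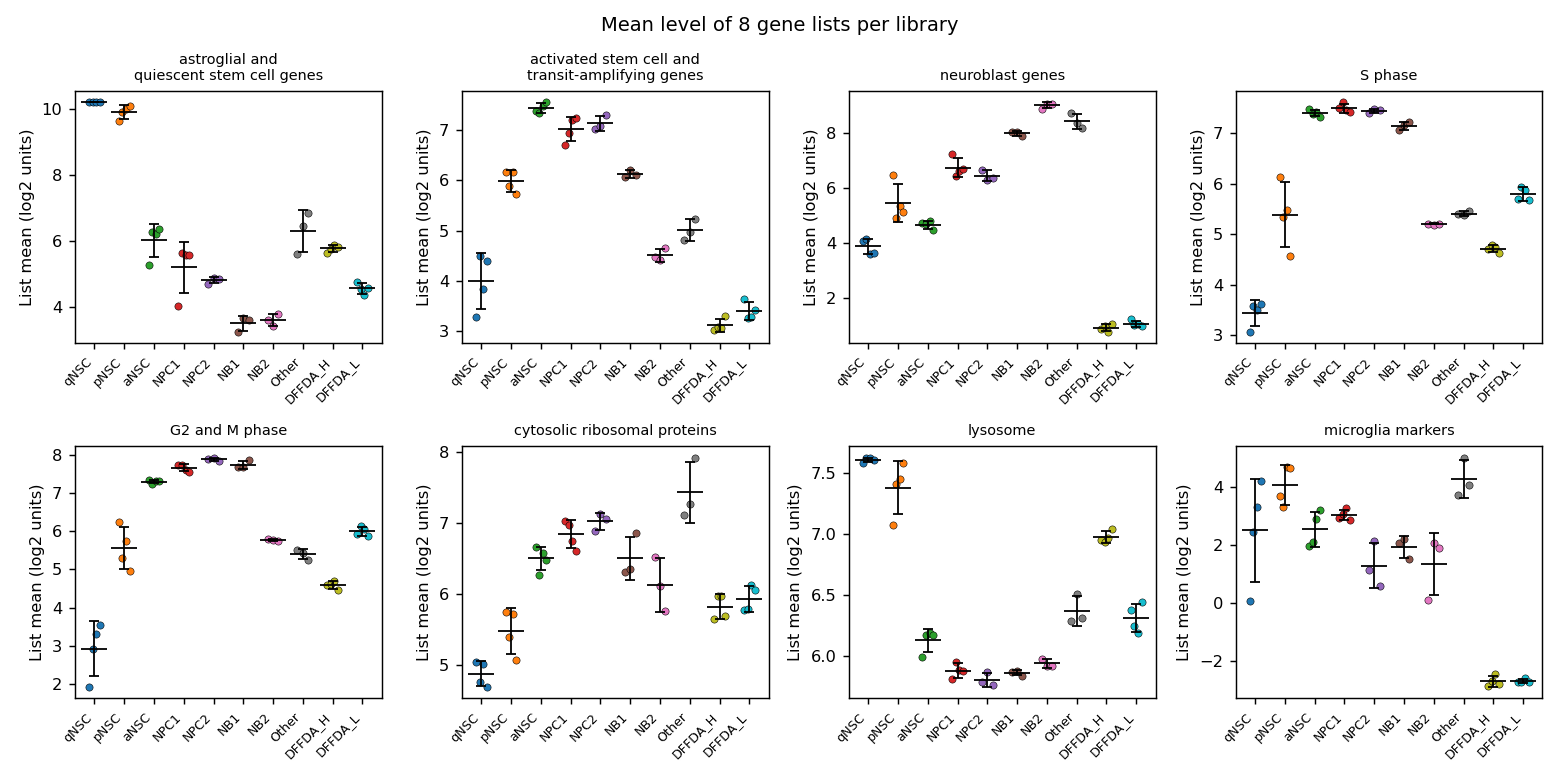
Mean log2 value of 8 gene lists (vertical axis) in each library by population (horizontal axis), with points for libraries and bars for mean ± SD. S phase genes average 3.44 in qNSC, 5.38 in pNSC and 7.4 in aNSC and fall from 7.15 in NB1 to 5.2 in NB2, while astroglial genes average 10.2 in qNSC and 3.5 in NB1.

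The passage from aNSC to NPC1 brought neuroblast transcripts up and stem cell surface, astroglial and Notch transcripts down, while Mki67 did not pass (limma adjusted p 0.81). The zinc finger genes St18 and Sp9, the synaptic gene Lrrtm3, the microtubule regulator Stmn2 (ENSMUSG00000027500, chromosome 3, 8509360 to 8561606), Igfbpl1 (ENSMUSG00000035551, chromosome 4, 45809468 to 45826923) and the noncoding Dlx6os1 had the largest increases, at log2 3.38 to 4.7. The homeobox gene Dlx5 was 9.24-fold higher. Dlx6os1 lies antisense to another gene, so its reads are uncertain. The receptor Tnfrsf19, Notum and the overlapping Myadml2os, Chrdl1 and Gna14 were among the largest decreases, at log2 -3.4 to -3.12. The call of Gna14 (0.00985) ended without NPC1 replicate 1 (0.0634). Egfr, Slc1a3 and Cd9 were lower in NPC1 by log2 -2.59, -2.42 and -0.908.

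Between aNSC and NPC1, 2262 genes changed, 1110 higher and 1152 lower in NPC1, 945 of them over 2-fold. Fitting only these 2 groups gave 5054 genes, library weights 5983 and removal of 3 doubted libraries of other groups 3907, while 1335 passed without NPC1 replicate 1. Cd24a lay just outside the threshold (limma adjusted p 0.0503; 0.00215 to 0.0794 over the alternatives) and passed without aNSC replicate 1 (0.0435) or NPC1 replicate 3 (0.0462) or 4 (0.0346). Prom1 (0.112), Tnfrsf1a (0.104), Cdkn1a (0.796), Cdkn1b (0.968) and Tnfrsf1b (0.845) did not pass, though over the alternatives Prom1 ran from 0.00895 to 0.232 and Tnfrsf1a from 0.00776 to 0.116.

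Neuroblast genes were higher in NPC1 in 21 of 26 (24 adjusted over the list alone; camera adjusted p 8.68e-28, adjusted p = 0.0433 with an estimated correlation). Surface antigens were lower in 3 of 5 (4 adjusted over the list alone; camera 1.42e-05, adjusted p = 0.0229 with an estimated correlation), which may follow from the sorting gates. Notch signalling genes were lower in 10 of 16 (12 adjusted over the list alone; camera 6.1e-07, adjusted p = 0.0511 with an estimated correlation), the effector Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371) by log2 -1.59 and the receptor Notch3 (ENSMUSG00000038146, chromosome 17, 32120820 to 32166852) by -3.61 with 1 NPC1 library at the floor. Astroglial genes such as Mlc1, at -1.94, were lower in 15 of 30 (22 adjusted over the list alone; camera 1.04e-12, adjusted p = 0.237 with an estimated correlation), with the matrix gene Cspg5 at -2.49 and Cpt1a at -1.51. Immediate early genes such as Nr4a1, at -1.62, were lower in 5 of 27, also adjusted over the list alone (camera 0.000685, adjusted p = 0.53 with an estimated correlation). Without NPC1 replicate 1, the library farthest from the others in several of these genes, these 5 lists still passed with camera. G2 and M phase genes shifted higher in NPC1 as a set, with 3 of 52 past the threshold and 2 adjusted over the list alone (camera 0.00398, adjusted p = 0.677 with an estimated correlation).

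In the fit of all freshly sorted populations, few genes were called between NPC1 and NPC2, most of them lower in NPC2. The count depended on the fit, with 239 genes and 156 to 2180 over the alternatives. Egfr was 2.53-fold higher in NPC2, at 8.51 ± 0.156 (n = 3) against 7.17 ± 0.36 (n = 4), and the matrix gene Spon1 (ENSMUSG00000038156, chromosome 7, 113765998 to 114043370) 2.52-fold. Tril was 2.94-fold higher. The transcriptional repressor Irf2bp2 (ENSMUSG00000051495, chromosome 8, 126588296 to 126593986) was lower by log2 -2.1, the splicing-related Pnisr by -1.69 and the matrix gene Sparc by -1.88. The stress-induced Dusp1 and Cyr61 were lower by -1.57 and -2.26. These 8 genes had limma adjusted p-values of 0.00557 or less and no overlap between the groups. Slc1a3 (0.671), Cd24a (0.507), Cd9 (0.634), Prom1 (0.945), Mki67 (0.665), Cdkn1a (0.881), Cdkn1b (0.703), Tnfrsf1a (0.79) and Tnfrsf1b (0.337) did not pass. Library weights passed Cd24a (0.00423; up to 0.582 over the alternatives) and Cdkn1b (0.0203; up to 0.814).

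The calls of the other genes named by size in this comparison lay near the threshold and ended when libraries were left out. Olfm2, 3.07-fold higher, lost its call without any 1 of the 7 libraries (limma adjusted p 0.0604 to 0.133), as did Igflr1, lower by -2.5 (0.051 to 0.134). Emp1 and Fbln2, 2.84-fold and 2.08-fold higher, lost theirs without any library except NPC1 replicate 3, reaching 0.189 without NPC2 replicate 1 and 0.177 without NPC2 replicate 3. Mark1, at -1.7, lost its call without any library except NPC1 replicate 1 (up to 0.153 without NPC2 replicate 1), and Dennd6b, at -1.84, without NPC1 replicate 2 (0.0523) or 4 (0.0569) or NPC2 replicate 1 (0.127) or 2 (0.0917).

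In this comparison 239 genes changed, 36 higher and 203 lower in NPC2, 135 of them over 2-fold. The count was 156 by limma without trend, 561 with only the 2 groups fitted, 621 without the 3 doubted libraries of other groups and 2180 with library weights. Leaving out 1 library gave 80 (NPC2 replicate 1), 96 (NPC1 replicate 4), 115 (NPC2 replicate 3), 117 (NPC1 replicate 3), 118 (NPC1 replicate 2) or 125 (NPC2 replicate 2). The 15.1% of calls that were higher was 27.1% with only the 2 groups fitted and 38.1% with library weights.

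Immediate early genes were lower in NPC2 in 7 of 27 (11 adjusted over the list alone; camera adjusted p 9.61e-13, adjusted p = 0.11 with an estimated correlation). Microglia markers fell by a median log2 of 1.62, with 1 gene past the threshold and 5 adjusted over the list alone (camera 1.92e-10, adjusted p = 0.23 with an estimated correlation). Of these Laptm5, at -2.45, lost its call without any library except NPC2 replicate 2 (up to 0.278 without NPC2 replicate 1), and Ptprc was listed at the floor in NPC2 (0.08; 0.000692 to 1 over the alternatives). Ependymal markers were lower in 2 of 16 (5 adjusted over the list alone; camera 0.00121, adjusted p = 0.127 with an estimated correlation) and did not pass with values below 0 set to 0 (0.154; 2.45e-05 to 0.392 over the alternatives). The ciliary gene Cfap44, near the floor, lost its call with values below 0 set to 0 (0.887; 0.00172 to 0.887 over the alternatives) and without NPC1 replicate 2 (0.0624) or 4 (0.0936) or NPC2 replicate 1 (0.201) or 3 (0.0578). Surface antigens shifted higher in NPC2 (camera 0.00188, adjusted p = 0.0433 with an estimated correlation), with Egfr alone past the threshold, also adjusted over the list alone. This too may follow from the sorting gates.

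From NPC2 to NB1, part of the Notch and progenitor transcripts fell and most listed neuroblast ones rose. With an estimated correlation the activated stem cell list kept its camera call, and the Notch and neuroblast lists lost theirs. Egfr fell by 2.98 on the log2 scale, Slc1a3 by 1.83 and Cd9 by 0.703. Hes6 fell by 1.93, Hes5 by 2.45 and Notch1 by 1.38. The ligand Wnt7b (ENSMUSG00000022382, chromosome 15, 85535437 to 85582473), Tnfrsf19, Me3, Zcchc24, Tmem132b and the phagocytosis bridge gene Mfge8 had the largest decreases, at log2 -3.63 to -3.18. The cation channel Trpc4, Stmn2, Mcub, Islr2, the GABA-synthesis gene Gad1 and Myt1l had the largest increases, at log2 3.01 to 4.75, and the guidance receptor Robo2 and Nrep were 6.3-fold and 5.55-fold higher. Limma gave these genes adjusted p-values of 0.00974 or less.

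Here 1364 genes changed, 673 higher and 691 lower in NB1, 781 of them over 2-fold. Fitting only the 2 groups gave 2690, removal of 3 doubted libraries of other groups 2511 and library weights 6234. Leaving out 1 library gave 764 (NB1 replicate 1), 800 (NPC2 replicate 2), 856 (NPC2 replicate 3) or 885 (NB1 replicate 2). Cd24a lay outside the threshold (limma adjusted p 0.0611; 0.000129 to 0.0995 over the alternatives). Prom1 (0.293; 0.00274 to 0.32), Mki67 (0.951), Cdkn1a (0.863), Cdkn1b (0.973), Tnfrsf1a (0.888) and Tnfrsf1b (0.284) did not pass.

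Neuroblast genes were higher in NB1 in 17 of 26 (19 adjusted over the list alone; camera adjusted p 4.5e-18, adjusted p = 0.092 with an estimated correlation), and mature neuron markers did not pass as a set (0.147). Lower were 6 of 13 activated stem cell genes (9 adjusted over the list alone; camera 6.55e-07, adjusted p = 0.0434 with an estimated correlation) and 16 of 30 astroglial genes, Slc1a2 at -1.56 among them (20 adjusted over the list alone; camera 5.14e-17, adjusted p = 0.146 with an estimated correlation). Ribosome biogenesis genes were lower in 10 of 30 (14 adjusted over the list alone; camera 7.66e-10, adjusted p = 0.0229 with an estimated correlation), Dkc1 at -0.85 and Ncl at -0.655, the latter not past without NPC2 replicate 2 (0.0599) or NB1 replicate 1 (0.0613). Notch signalling genes were lower in 6 of 16 (7 adjusted over the list alone; camera 0.000206, adjusted p = 0.127 with an estimated correlation). The glycolytic gene Ldha was lower by -1.31.

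NB2 differed from NB1 by a fall of most listed cell cycle transcripts and a rise of part of the neuroblast ones. None of these lists kept its camera call with an estimated correlation. The prokineticin receptor Prokr2 (ENSMUSG00000050558, chromosome 2, 132337733 to 132385447), which migrating olfactory neuroblasts need, the adhesion gene Ncam2, Syt6, the imprinted noncoding Meg3, the semaphorin receptor Plxna4 (ENSMUSG00000029765, chromosome 6, 32144268 to 32588192) and Runx1t1 had the largest increases, at log2 4.22 to 6.11. Robo2, Gad1 and the microtubule gene Dcx were 7.56-fold, 4.36-fold and 3.72-fold higher. Gsx1, Gjc1, Rrm2 (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146), Cdc6, Ednrb and Ccne1 had the largest decreases, at log2 -4.23 to -3.22. Egfr fell by 1.8, Mki67 by 1.66, Slc1a3 by 1.08, Prom1 by 0.893 and Cd9 by 0.682. Limma gave these adjusted p-values of 0.00381 or less.

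Of the genes tested between NB1 and NB2, 4371 changed, 1842 higher and 2529 lower in NB2, 2480 of them over 2-fold. The count was 6557 with only the 2 groups fitted and 9015 with library weights. The share of calls that were higher, 42.1%, was 49.8% with only the 2 groups fitted and 51.7% under trimmed-mean centring, which moved the median over all genes from -0.026 to 0.06. Cdkn1a was lower by -1.38 (limma adjusted p 0.0169), a call that ended without NB1 replicate 3 (0.0501) or NB2 replicate 2 (0.0687) or 3 (0.0553). Cdkn1b did not pass (0.0807; 0.00027 to 0.187 over the alternatives) but did without NB1 replicate 3 (0.00632). Cd24a (0.317; 0.0167 to 0.365), Tnfrsf1a (0.538) and Tnfrsf1b (0.295) did not pass.

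In NB2, 37 of 42 S phase genes were lower, Mcm4 by -2.23 among them (39 adjusted over the list alone; camera adjusted p 1.28e-27, adjusted p = 0.0511 with an estimated correlation). G2 and M phase genes such as Hmgb2 and Cdk1, at -2.85 and -2.56, were lower in 45 of 52 (49 adjusted over the list alone; camera 6.61e-26, adjusted p = 0.0738 with an estimated correlation). Oxidative phosphorylation genes such as Cycs and Cox5a, at -1.4 and -1.11, were lower in 31 of 46 (35 adjusted over the list alone; camera 3.03e-10, adjusted p = 0.458 with an estimated correlation). Cholesterol synthesis genes such as Msmo1 and Fdps, at -1.57 and -1.13, were lower in 14 of 21 (16 adjusted over the list alone; camera 1.42e-06, adjusted p = 0.0888 with an estimated correlation), and the fatty acid oxidation gene Hadh by -1.92. Neuroblast genes were higher in 12 of 26 (15 adjusted over the list alone; camera 1.77e-06, adjusted p = 0.443 with an estimated correlation). Mature neuron markers were higher in 4 of 16, also adjusted over the list alone (camera 0.0436, adjusted p = 0.53 with an estimated correlation), a call that also ended under 6 other alternatives (0.0686 to 0.186) and without NB1 replicate 1 (0.073) or NB2 replicate 3 (0.0564).

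**Figure D4:**
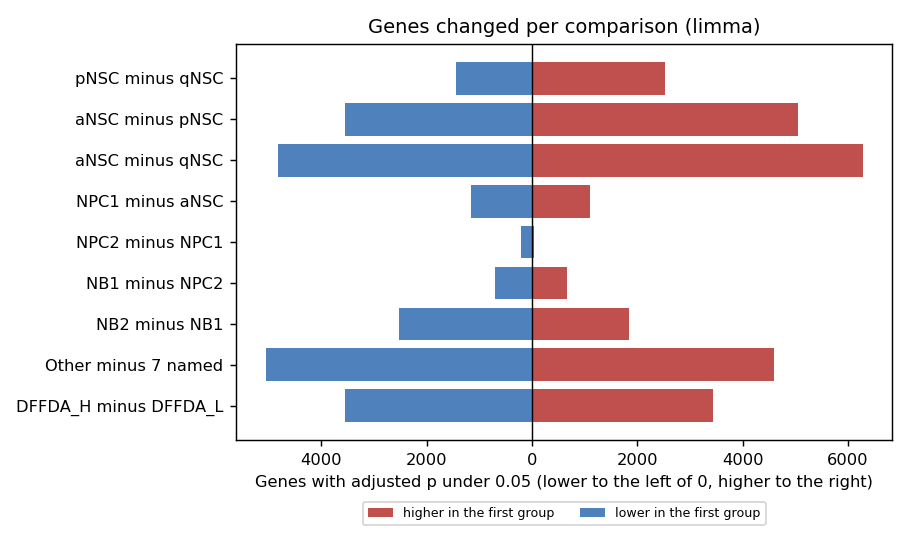
Number of genes with limma adjusted p under 0.05 in each of the 9 comparisons (horizontal axis, genes, lower to the left of 0 and higher to the right). Bars are counts, from 239 genes for NPC2 against NPC1 to 11090 for aNSC against qNSC. Their order depends on the fit: with only the compared groups fitted, the count for qNSC to pNSC fell below that for aNSC to NPC1.

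The population labelled Other carried blood vessel and mural cell transcripts along with neuroblast ones, against the mean of the 7 named populations (n = 3 against 25). The tight junction gene Cldn5, the vessel genes Ly6a, Ly6c1 and Car4, the amino acid transporter Slc38a5 and the matrix gene Vtn (ENSMUSG00000017344, chromosome 11, 78499091 to 78502324) had the largest increases, at log2 9.25 to 10.3, with 4 to 17 of the other libraries at the floor. The membrane gene Itm2a (ENSMUSG00000031239, chromosome X, 107397099 to 107403376), with none at the floor, averaged 9.63 ± 0.71 in Other and 2.76 in the 7 others, 117 times as high (limma adjusted p 3.33e-14), and Eng was 42.3-fold higher. The pericyte genes Rgs5 (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813) and Higd1b rose by log2 8.31 and 8.12, again with other libraries at the floor. Tubb3 and Stmn2 were 8.75-fold and 18.7-fold higher. The separase gene Espl1, the pyrimidine synthesis gene Cad, the receptor kinase Tyro3, Inppl1, Rasa3 and Wdr90 had the largest decreases, at log2 -3.42 to -2.93.

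Against the named populations 9654 genes changed, 4603 higher and 5051 lower in Other, 5329 of them over 2-fold, and 5682 passed among genes with a mean of at least 4. Egfr, Mki67 and Slc1a3 were lower by log2 -3.44, -1.72 and -1.41. Cd24a, Cdkn1a, Cdkn1b and Prom1 were 4.65-fold, 3.42-fold, 2.59-fold and 1.89-fold higher, each with limma adjusted p of 4.89e-05 or less. Cd9 did not pass (0.0678; 7.59e-05 to 0.106 over the alternatives) but did without NB1 replicate 1 (0.0462) or Other replicate 3 (0.011), and Tnfrsf1a (0.172) passed without Other replicate 2 (0.0182). Tnfrsf1b was 6.68-fold higher (0.0235), with 5 of the other libraries at the floor, a call that ended without Other replicate 2 (0.112) or 3 (0.0765).

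All 19 endothelial markers were higher in Other, also adjusted over the list alone (camera adjusted p 2.83e-14, adjusted p = 0.0252 with an estimated correlation), as were all 8 mural cell markers, again also adjusted over the list alone (camera 9.52e-05, adjusted p = 0.0511 with an estimated correlation). The mural marker Pdgfrb, though above the mean of the named populations, averaged less in Other (3.85) than in qNSC (7.11) and pNSC (5.86). Neuroblast genes were higher in 24 of 26, also adjusted over the list alone (camera 1.86e-12, adjusted p = 0.165 with an estimated correlation). Ribosomal protein genes such as Rps27, 3.82-fold, were higher in 78 of 79, also adjusted over the list alone (camera 3.8e-27, adjusted p = 0.299 with an estimated correlation). Microglia markers such as P2ry12 and C1qb, 3.62-fold and 6.64-fold, were higher in 14 of 20 (15 adjusted over the list alone; camera 0.00098, adjusted p = 0.586 with an estimated correlation). Interferon and antigen presentation genes such as B2m and H2-K1, 6.51-fold and 4.7-fold, were higher in 15 of 26, also adjusted over the list alone (camera 0.00229, adjusted p = 0.599 with an estimated correlation). Immediate early genes such as Klf2 and Ier3, 10.2-fold and 26.8-fold (the latter with qNSC replicate 1 at the floor), were higher in 15 of 27, also adjusted over the list alone (camera 0.00669, adjusted p = 0.599 with an estimated correlation). Among genes with a mean of at least 4 the microglia, interferon and immediate early lists did not pass (0.165, 0.246 and 0.0709; over the alternatives from 5.41e-05 to 0.586, 0.000318 to 0.599 and 0.00124 to 0.599). Erythroid markers were higher in 4 of 5, also adjusted over the list alone, without passing as a set (0.145), and oligodendrocyte and mature neuron markers did not pass (0.559 and 0.535).

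In culture, DFFDA_H cells had fewer cell cycle transcripts and more astroglial and lysosomal ones than DFFDA_L cells, 2 populations that the design text says differ in proliferative kinetics. Most members of these lists passed singly, but none of the lists kept its camera call with an estimated correlation. Mki67 was lower by log2 -2.41 in DFFDA_H, at 3.68 ± 0.294 against 6.09 ± 0.266 (SD, n = 4 each). The lipid carrier Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) and the astrocyte water channel Aqp4 (ENSMUSG00000024411, chromosome 18, 15389496 to 15410982) were 13.6-fold and 18 times as high. The matrix gene Thbs2 (ENSMUSG00000023885, chromosome 17, 14665500 to 14694235), Gstt3, the glutamate receptor Gria1 and the cholesterol exporter Abca1 were also among the 6 largest increases, at log2 3.65 to 6, and Clu was 11.6-fold higher. The carbonic anhydrase Car3, Gjc1, Moxd1, the glycolytic Hk2 and the kinesin Kif15 joined Mki67 among the largest decreases, at log2 -2.55 to -2.36. The TNF receptor Tnfrsf1a was 1.83-fold higher and Prom1 lower by -1.79. Limma gave these genes adjusted p-values of 0.000531 or less with no overlap between the groups.

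Of 15956 genes tested, 6995 changed in the neurosphere comparison, 3442 higher and 3553 lower in DFFDA_H, 1837 of them over 2-fold. The count was 3220 when all 36 libraries were fitted together and 4318 among genes with a mean of at least 4. Cdkn1a was 1.42-fold higher (limma adjusted p 0.00558) and Cd24a lower by -0.361 (0.0134). The fit of all 36 libraries ended both calls, at 0.315 and 0.434, the top of their ranges from 0.0014 and 0.00861 over the alternatives, and that of Moxd1, at 0.0894 (1.44e-07 to 0.0894). Slc1a3 (0.855), Cd9 (0.821) and Egfr (0.208) did not pass, and Cdkn1b (0.0743) did only without DFFDA_L replicate 2 (0.02) among the libraries left out. Tnfrsf1b was below the filter and not tested.

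Lower in DFFDA_H were 40 of 42 S phase genes, Rrm2 by -1.44 among them, also adjusted over the list alone (camera adjusted p 7.53e-22, adjusted p = 0.127 with an estimated correlation). G2 and M phase genes such as Tpx2 and Kif2c, at -1.65 and -2.13, were lower in 51 of 52, also adjusted over the list alone (camera 8.68e-28, adjusted p = 0.0733 with an estimated correlation). Ribosome biogenesis genes such as Dkc1 and Ncl, at -1.08 and -1.16, were lower in 25 of 30 (27 adjusted over the list alone; camera 6.62e-09, adjusted p = 0.0434 with an estimated correlation). Cholesterol synthesis genes such as Lss, at -1.04, were lower in 15 of 21 (17 adjusted over the list alone; camera 1.42e-06, adjusted p = 0.208 with an estimated correlation). Oligodendrocyte precursor markers such as Tnr and Vcan, at -2.3 and -1.19, were lower in 7 of 8, also adjusted over the list alone (camera 0.000777, adjusted p = 0.292 with an estimated correlation), and missed the threshold among genes with a mean of at least 4 (0.085; 3e-04 to 0.292 over the alternatives).

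Higher in DFFDA_H were 19 of 27 astroglial genes (22 adjusted over the list alone; camera adjusted p 2.86e-09, adjusted p = 0.127 with an estimated correlation). Lysosome genes such as Hexa and Cd63, 2.36-fold and 2.09-fold, were higher in 23 of 28 (25 adjusted over the list alone; camera 6.04e-13, adjusted p = 0.144 with an estimated correlation). Fatty acid oxidation genes such as Acadvl, 1.74-fold, were higher in 16 of 22 (18 adjusted over the list alone; camera 1.02e-05, adjusted p = 0.122 with an estimated correlation). Mitochondrially encoded transcripts such as mt-Nd2, 2.25-fold, were higher in 5 of 8, also adjusted over the list alone (camera 0.0218, adjusted p = 0.443 with an estimated correlation), and just missed the threshold with GC and length trends removed (0.0529; 0.00394 to 0.443 over the alternatives). B2m and the matrix gene Sdc4 were 1.7-fold and 3.3-fold higher.

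The neurosphere difference ran along the difference between qNSC and aNSC. Across 14586 genes tested in both, the change from DFFDA_L to DFFDA_H correlated with that from aNSC to qNSC at Spearman's rho 0.522 and Pearson's r 0.529, and 69.9% of genes had the same sign. Of the genes called in both, 1874 were higher in both qNSC and DFFDA_H where 860 would fall by independence, and 2339 were lower in both where 1277 would. Another 275 and 320 went opposite ways, where 900 and 1221 would. Genes are not independent replicates, so these correlations carry no p-value here.

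**Figure D5:**
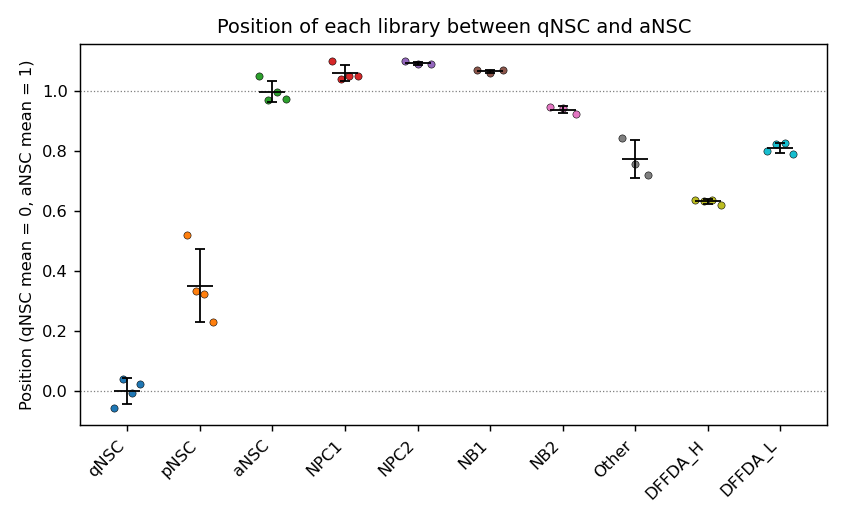
Position of each library between qNSC (mean 0) and aNSC (mean 1), without unit, on the vertical axis by population on the horizontal axis, with points for libraries and bars for mean ± SD. The 4 DFFDA_H libraries lie between 0.622 and 0.639, below the 4 DFFDA_L libraries at 0.792 to 0.826.

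On the scale from qNSC at 0 to aNSC at 1, built from 6276 genes higher and 4814 lower in aNSC, the pNSC libraries averaged 0.352 ± 0.12 (SD, n = 4) and ranged from 0.229 to 0.522. NPC1, NPC2 and NB1 lay at 1.06, 1.09 and 1.07, NB2 at 0.938 and Other at 0.774. DFFDA_H averaged 0.634 ± 0.0078 and DFFDA_L 0.811 ± 0.017 (n = 4 each). The difference of -0.177 had an exact two-sided permutation p of 0.0286, the smallest that the 70 arrangements of these 8 libraries, taken as unpaired, can give. With equal replicate numbers as pairs the exact p was 0.125, the smallest that 16 arrangements can give. Whether the libraries are paired is not known.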

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

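The test for libraries standing apart, and its limit, were fixed before any values were seen, and no test of its causes was added afterwards. In groups of 4 libraries, a value was singled out when its gap to the nearest other library, as a share of the range of the group, passed the 95% limit of Dixon's test. Of 317 sets of 4 values examined, for the named genes, the positions, the genes at the floor and the step between values, 32 had a library apart, 31 of them gene values. Chance flags about 1 in 20 groups. Replicate 1 was the library apart in 21 of the 32, which comprised all 7 in NPC1, 5 of 6 in qNSC, 6 of 8 in aNSC and 3 of 5 in pNSC. DFFDA_L and DFFDA_H had 3 each, none of replicate 1. Genes within a library vary together, so these are not separate events, and no biological explanation was tested, since the labels give nothing that sets replicate 1 apart.

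In NPC1, the position of replicate 1 on the scale from qNSC (0) to aNSC was 1.1 (nearest other library 1.05). The zinc finger gene St18 stood at 6.82 (nearest other library 5.33) and Dlx6os1 (ENSMUSG00000090063) at 9.06 (7.75). The astroglial and Notch genes were low in it, with Slc1a3 at 7.34 (8.32), Mlc1 at 5.1 (6.24), Hes5 at 3.53 (4.69) and Cspg5 at 4.03 (6.17).

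In aNSC, replicate 1 had Myadml2os at 5.76 (nearest other 6.71), Notum at 6.56 (7.52), Mlc1 at 7.44 (8.02) and Id3 at 3.62 (4.65), and was high in Dll3 at 7.87 (7.53) and Cdkn1a at 6.42 (5.99). Replicate 4 of aNSC had Atp13a4 at -1.82 and Gjb2 at -2.99 where the nearest other library was at -4.71 for both, all values near the floor.

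In qNSC, replicate 1 had Aurkb and Dtl at its floor of -2.18 (nearest others 1.8 and 2.41), Rarb at 5.32 (4.73), Dlx2 at 5.98 (5.54) and Tpp1 at 8.44 (8.68). Replicate 3 had Agt at 7.12 (7.23), a small gap in a tight group. In pNSC, replicate 1 had Stambpl1 and Dll4 at its floor of -3.74 (2.6 and 2.57) and Id3 at 7.39 (8.2), and replicate 3 had Tnfrsf1b at -4.31 (1.46).

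Among the neurosphere libraries, DFFDA_L replicate 4 had Mki67 at 5.69 (nearest other 6.2) and Vcan at 5.16 (5.43), and DFFDA_L replicate 2 had Tpx2 at 6.83 (6.62). DFFDA_H replicate 2 had Apoe at 10.1 (10.4), replicate 3 Car3 at 8.28 (7.47) and replicate 4 Kif2c at 2.96 (3.2). None of these 6 values reaches the range of the other neurosphere population for its gene, as the groups did not overlap.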

How the results depend on the processing

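Library weights, a common floor, trimmed-mean centring, removal of 3 doubted libraries, removal of GC and length trends, a higher filter and the paired test of positions were chosen after the data were seen, and the other alternatives before. Of 3149 results of named genes over the alternatives, 3070 kept their side of the threshold and their direction, 37 lost a call, 42 gained one and none turned. Of 1131 results of called lists over the alternatives other than the estimated correlation, 1066 kept theirs, 63 lost a call and 2 turned. With 1 library left out, 2881 of 2962 gene results and 1083 of 1134 list results kept theirs. The lists passing were 15 with an estimated correlation and 182 by the mixed fry test, which asks for change either way, against 116. Those that turned were both for NPC2 against NPC1 among genes with a mean of at least 4, the ependymal markers (adjusted p 0.392) and the mature neuron markers (0.855).

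With only the compared groups fitted, changed genes numbered 1380 from qNSC to pNSC, 5054 from aNSC to NPC1, 561 from NPC1 to NPC2, 2690 from NPC2 to NB1 and 6557 from NB1 to NB2, and 3220 between DFFDA_H and DFFDA_L when all 36 libraries were fitted. The spread shared by the fit differs between these. Libraries were less alike in qNSC, pNSC and Other, with lowest correlations of 0.879, 0.901 and 0.922, than in the other sorted populations (0.952 or more). A spread pooled over all of them is likely too small for qNSC against pNSC and too large for the closer populations. The order of the counts depended on the fit, since qNSC to pNSC fell below aNSC to NPC1. How much the pooled spread accounts for was not tested further. Library weights gave 2234, 5983, 2180, 6234 and 9015 for the same 5 freshly sorted steps. Removing qNSC replicate 1, pNSC replicate 1 and Other replicate 3 gave 3907 from aNSC to NPC1, 621 from NPC1 to NPC2 and 2511 from NPC2 to NB1. These 3 libraries lie outside the groups compared in those steps, so group means stayed and only the spread estimated by the fit could change. Limma without trend gave 156 from NPC1 to NPC2. For the weights and the trend the cause was not tested. Testing only genes with a mean of at least 4, which are fewer, gave 5314 from pNSC to aNSC, 6539 from qNSC to aNSC, 5682 for Other and 4318 for DFFDA_H against DFFDA_L.

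Leaving out 1 library gave 2429 (without pNSC replicate 1) to 4464 genes from qNSC to pNSC, 7572 to 9009 from pNSC to aNSC, 10351 to 11036 from qNSC to aNSC, 1335 (without NPC1 replicate 1) to 2128 from aNSC to NPC1 and 80 to 193 from NPC1 to NPC2, where 96 (NPC1 replicate 4), 115 (NPC2 replicate 3), 117 (NPC1 replicate 3), 118 (NPC1 replicate 2), 125 (NPC2 replicate 2) and 80 (NPC2 replicate 1) lay below the 1.5-fold limit. It gave 764 (NB1 replicate 1), 800 (NPC2 replicate 2), 856 (NPC2 replicate 3) and 885 (NB1 replicate 2) up to 1227 from NPC2 to NB1, 3047 to 3946 from NB1 to NB2, 7662 to 10303 for Other and 5706 to 6971 for the neurosphere groups. The agreement between the neurosphere and sorted differences was 0.602 over called genes only and 0.515 without cell cycle lists, and the position difference stayed within -0.16 to -0.183. Removing those lists left 14492 of 14586 genes, so it cannot separate the agreement from proliferation. The called genes were chosen by the sorted difference itself, which can raise the value.

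The replicate number as a block gave counts of 4103, 8633, 11153, 2408, 211, 1472, 4497, 9561 and 6864 for the 9 comparisons, in order. With equal numbers as pairs, the position difference of -0.177 between the neurosphere groups had an exact p of 0.125, the smallest that 16 arrangements can give. The labels do not say that equal numbers share an animal or culture. Deviations of equally numbered libraries from their group means correlated at -0.16 to 0.24, not above 0.1 in every pair of any comparison. Libraries that correlated best with their own number were 7 of 8 for qNSC and pNSC and 8 of 8 for pNSC and aNSC. They were 6 of 8 for qNSC and aNSC, 6 of 8 for aNSC and NPC1 and 6 of 6 for NPC1 and NPC2. They were 2 of 6 for NPC2 and NB1, 0 of 6 for NB1 and NB2 and 3 of 8 for the neurosphere groups. Equally numbered neurosphere libraries were also alike in Xist and Ddx3y. Most libraries from qNSC to NPC2 matched their own number, more than unrelated numbers would be likely to give, though the correlations were small. Something shared by equal numbers is therefore likely in those populations. It was not seen between NPC2 and NB1 or between NB1 and NB2. Whether it is an animal or a culture is not given. Pairing is therefore neither established nor excluded, and the unpaired tests would ignore it. A grouping of the neurosphere libraries by their Xist values was also tried and set aside, since it groups samples by a measured value and not by a label. Voom, thinning to a common depth, another pseudocount and count-based tools need counts and were not run.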

Other observations

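The Cx3cr1 test and the removal of GC and length trends, the common floor and the higher filter used in the tests here were chosen after the results were seen, and the other tests before. The phosphatase regulator gene Ppp1r1b was abundant in qNSC and pNSC, at log2 8.3 ± 0.074 and 7.82 ± 0.37 (SD, n = 4 each), against 0.646 ± 1 in aNSC. The dopamine receptor Drd2 was low, at -2.35 ± 1.8 in qNSC with 2 libraries at the floor, and at -0.065 ± 0.31 in aNSC with none there. Penk averaged 2.48 ± 1.4, -0.511 ± 2.2 and 0.509 ± 0.79 in qNSC, pNSC and aNSC. The pericyte receptor Pdgfrb averaged 7.11 ± 0.2 in qNSC and 5.86 ± 1.1 in pNSC, above its 3.85 ± 1.9 in Other, where mural genes such as Vtn (8.93 ± 2.1), Rgs5 (5.77 ± 1.4) and Higd1b (4.55 ± 2.4) were present. In qNSC these 3 averaged 0.452 ± 2.2, 0.478 ± 1.8 and -1.06 ± 1.2. The adenosine receptor Adora2a averaged 3.24 ± 0.59 in qNSC and -4.09 ± 0.73 in aNSC, and 5.24 ± 0.19 in DFFDA_H against 3.86 ± 0.39 in DFFDA_L. These genes were chosen after their values were seen.

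Of the neurosphere libraries, replicates 2 and 4 of both populations had Xist at log2 6.19 to 6.59 and Ddx3y at -4.18 to -2.13, and replicates 1 and 3 had Xist at -4.79 to -4.23 and Ddx3y at 5.94 to 6.31. All freshly sorted groups had both transcripts. No comparison reported here uses these values.

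Ribosomal protein transcripts were higher in aNSC than in qNSC by a median log2 of 1.66 (95% interval 1.56 to 1.75, 79 genes). Other genes matched for length, GC and level had a median of 0.232 (0.0506 to 0.458, 330 genes), which argues against such a bias as the whole cause. Both intervals come from resampling genes, which are not independent replicates, and they leave out the spread between libraries. The median was 1.74 without qNSC replicate 1 (camera adjusted p 1.07e-17, though with all libraries the list did not pass with an estimated correlation, at 0.464), which argues against that library. It was 1.69 among the 37 genes with no named pseudogene in the table. Pseudogenes under other names or absent from the table were not counted, so this cannot decide on reads shared with pseudogenes, which stay open. Higher ribosomal protein transcript levels in aNSC may be a property of these cells, a hypothesis found and tested on the same data. A change in total RNA per cell stays open, since quantile normalization hides it.

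Microglial transcripts were higher in pNSC than in qNSC, by a median log2 of 1.87 over 20 genes, most of which did not pass singly. The list's camera call (adjusted p 0.000723) ended with an estimated correlation (0.586), with library weights and among genes with a mean of at least 4. A second list of 25 microglial genes, of which 1 has a mean of at least 4 in aNSC, had a median of 1.52 with 22 positive changes, 4 called higher and 0 lower, at percentile 100 of 10000 matched random lists. Those lists were matched on level only. Genes of a cell type can vary together, so an extreme percentile can arise from the spread between libraries. The second list was not refitted without qNSC replicate 1. Microglial cells or their RNA in the sort may contribute. Of the most abundant list genes Cx3cr1 stood at 7.54 in pNSC and 7.02 in qNSC, and Csf1r at 6.46 and 4.57. Cx3cr1 also averaged 5.37 in DFFDA_H and 5.38 in DFFDA_L, where C1qa was at the floor, so it does not follow microglial RNA alone. One deviating library may also contribute, since the median was 0.837 without qNSC replicate 1 and 1.87 without pNSC replicate 1, while 1.48 with values below 0 set to 0 argues against the floor as the whole cause. The gates that would remove microglia are not given in the sources used here, and the explanations with values in their favour stay open together.

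Calls between NPC1 and NPC2 were lower in NPC2 in 84.9%. The share was 81.7% among genes with a mean of at least 4 and 79.5% with GC and length trends removed, which argues against the floor and depth and against length or GC bias as the whole cause. Leaving out the lists of other cell types and immediate early genes removed 11 calls, too few to decide, and left 84.2% of 228. Microglia markers were lower by a median log2 of 1.62, with only Laptm5 past the threshold. Their camera call (adjusted p 1.92e-10) ended with an estimated correlation (0.23). Fewer cells of other types in the NPC2 sort therefore stays open without being shown. The share was smaller with library weights, where 38.1% of calls were higher. The labels give no difference between these populations beyond their names, so no biological explanation was tested.

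The microglial receptor gene Cx3cr1 was read in every library. Where C1qa, C1qb and Tmem119 were all below 0, in the 8 neurosphere libraries and no others, Cx3cr1 was at 5.15 to 5.5, against 6.65 to 7.79 in freshly sorted libraries, and microglial cells or their RNA are therefore argued against there. Its model on chromosome 9 from 119901616 to 120069879 overlaps 9 other genes, 5 of them protein coding, so its reads may come from these, which was not tested.

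Libraries were also divided in other ways, to see whether any division gives such counts. For qNSC against pNSC the real split gave 3959 genes and the highest other 1210, over 35 splits that include the real one, so 1 split reached the real count, the real one. For pNSC against aNSC the values were 8585 and 3175, for qNSC against aNSC 11090 and 375, for aNSC against NPC1 2262 and 4, for NPC1 against NPC2 239 and 47, and for DFFDA_H against DFFDA_L 6995 and 2, with 35 splits and 1 as large in each, the real one, which argues against an arbitrary division as the source of those counts. For Other a fit of 2 groups gave 3742 against 3054 as the highest of 100 drawn splits, 1 as large, the real one. The other draws mixed libraries of different populations, and most gave no genes. The 3054 came from qNSC replicates 1 and 4 with pNSC replicate 1. The draws therefore cannot tell whether another single population set against the rest would give as many. The agreement of the neurosphere with the sorted difference, 0.522, exceeded 0.497, the highest of the others among 35 splits, again with 1 as large, the real one. The 10 splits for NPC2 against NB1 (1364, highest other 1) and NB1 against NB2 (4371, highest other 2) are too few for a share under 0.05. The highest other split for qNSC against pNSC put qNSC replicate 1 with pNSC replicates 1 to 3, and that for pNSC against aNSC put pNSC replicate 1 among aNSC.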
